A study of Mus musculus with 2 samples.

How the data were processed

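RNA was measured on the 10x Visium array in 1 coronal brain section from each of 2 mice (mouse 1 and mouse 2 are replicates 1 and 2 of 1 group). Per the labels, both mice expressed hM3Dq and were given CNO. The brains were dissected without perfusion and fresh frozen, sections were 10 µm thick, the capture area was 6.5 mm wide, and permeabilisation took 12 min. The values deposited by the authors are counts: whole UMI counts per gene and spot, made with Space Ranger 1.3.1 per the file headers, on the mm10 build per the submitters' processing notes. Aligner settings and the annotation version are not given in the sources used here. The tables hold 32285 genes, of which 13 are mitochondrial, and 78 carry a symbol shared with another gene and were not matched by symbol. Image scale factors were not used here, since positions were taken in image pixels and distances in spot pitches.

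Mouse 1 had 3715 spots under tissue, of which 3712 with at least 500 UMIs were used, and mouse 2 had 3549, of which 3548 were used. Mitochondrial genes took 13.33% and 15.38% of the UMIs. Depth sets the precision: the C1ql2 region, the smallest, held 497834 UMIs in mouse 1 and 1525576 in mouse 2, so that C1qa had 28 and 83 UMIs there.

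Comparisons, gene lists, the naming rule and most alternatives were fixed before the data were examined. Spots of both sections were clustered together with scanpy 1.11.5 in Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9; figures with matplotlib 3.10.9). Counts were scaled to 10000 per spot and logged, 2000 variable genes seen in at least 20 spots were kept, and 30 principal components, 15 neighbours and Leiden resolution 1 were used. The 249 listed genes, of which 248 were among the symbols, were left out of clustering. A cluster took the name of the best of 18 marker sets when at least 3 markers were among its 100 leading genes, ranked by fold with 20 CPM added; the limit of 100 was chosen after the data were seen. The image side of each spot came from the line that best mirrored the clusters, tilted by -3.5 and 1.5 degrees, which matched 69.21% and 78.51% of mirrored spots.

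UMIs were summed per mouse and region, which gave 4 libraries and 1 residual degree of freedom per fit. Spots were not treated as replicates. Genes were tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr, mouse as a block) at a Benjamini-Hochberg threshold of 0.05. The prior degrees of freedom were 753 for the sides of the hippocampal regions, 30.4 for those of the C1ql2 region and unbounded elsewhere, so the tests rest on a spread pooled over genes. The SE of a log2 value is its size divided by the square root of the quasi-likelihood F statistic. It rests mainly on the same pooled spread and does not give the spread between the mice. Lists with at least 3 tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and with an estimated one. With 1 residual degree of freedom, the estimated version had little chance of calling any list, so its lack of calls decides nothing. Values in single mice used a prior count of 2. Ratios of counts have exact Poisson intervals of 95%, and a count of 0 was given an upper limit of 3 counts. The mice were compared without a test, on genes with at least 200 UMIs (50 for listed genes) and with 0.5 UMIs added; medians of lists were placed among 10000 random lists drawn from 20 expression bins.

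The 22 lists were classical complement, complement regulators and receptors, immunoglobulin genes, B and plasma cells, Fc receptors and adaptors, homeostatic microglia, activated or phagocytic microglia, border macrophages, astrocytes, reactive astrocytes, immediate early genes, late activity-regulated genes, presynaptic, excitatory postsynaptic, inhibitory neurons and synapses, phagocytosis signals, oligodendrocyte precursors, endothelium and pericytes, blood, interferon response, stress and RNA quality, and sex-linked and substrain genes. In region comparisons C1qa, C1qb and C1qc were always named, with up to 3 genes per list of the largest change past the threshold, at most 30 per comparison. Lists with no such gene gave up to 2 of their most abundant genes as values. Between sides the 10 largest rises and falls past the threshold with both mice in the same direction were named, with C1q genes, Fos, Arc, Npas4 and Egr1. Between mice the 10 highest and 10 lowest ratios with one sign in every region were eligible, with up to 3 genes per list. A further 23 pairs of gene and comparison were followed after their values were seen. In 3 comparisons, 1 gene that the rule picked is not reported and was left out of the numbers of genes followed.

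The fits were tested on simulated data with a dispersion of 0.02 for all genes and 200 changed genes. The fits to the data gave common dispersions between 0.00148 and 0.00649, so simulated recovery is not that of the data. With 1 dispersion for all genes, the false calls do not test whether the pooled spread suits the data. Recovery of 2-fold changes was 18.6% for the C1ql2 against the CA-set regions, 42.9% for the Ddn region, 59.1% against the neocortical, 73.8% against the thalamus-set and 46% against the white matter regions, and 48.5% for the hippocampal sides. Recovery of 4-fold changes lay between 83.6% and 98.5%, and false calls between 0% and 6.7%.

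Alternatives were DESeq2 1.42.0, DESeq2-style size factors in edgeR, no low-count filter, no mouse term, each mouse alone, thinning to the shallower library, no UMI minimum or 2000 UMIs, Leiden resolutions of 0.6 and 1.5, each section clustered alone, regions by marker scores, all regions in 1 fit, mouse 2 mirrored, the midline moved or a strip of 3 spot pitches left out, and scaling without mitochondrial genes. Foci were single or touching spots (within 1.3 pitches) with at least 10 UMIs of 10 antibody genes, and spots within 2.3 pitches were left out with them. The 10 genes were Igkc, Igha, Jchain, Ighg1, Ighg2b, Ighg2c, Ighg3, Iglc1, Iglc2 and Iglc3, without Ighm. Gene set and limits were chosen after the counts were seen. Clec7a is not among the symbols and Nnt shares one, so neither was measured. Clusters of the hypothalamus, habenula, meninges and reticular thalamus sets were left out of the comparisons, which did not call for them.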

Results

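The data were 2 spatial transcriptomes, each made from 1 coronal brain section of 1 mouse with the 10x Visium assay, which counts RNA molecules by unique molecular identifiers (UMIs) at barcoded array spots wider than a cell. Both mice expressed hM3Dq, an engineered receptor switched on by the drug CNO. The injection was at 4.6 mm posterior to bregma, and both mice were given CNO. The sections were 10 µm thick, lay 1.9 mm posterior to bregma and held the dorsal hippocampus of both sides. The mice form 1 group (n = 2) and no untreated section was measured, so every comparison is between regions, sides or mice of the treated group. Their genotype labels differ: mouse 1 was a C57BL/6J control and mouse 2 a CRISPR-Cas9 edited isogenic control. Mouse 1 gave 30671753 UMIs over 3715 spots under tissue, with a median of 7547 UMIs and 2848 genes per spot. Mouse 2 gave 55315952 UMIs over 3549 spots, with a median of 14663 UMIs and 4364 genes per spot.

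Spots were grouped into 19 clusters by genes outside the lists examined here, and 18 clusters were named by marker sets. The C1ql2 region carried 7 of 8 dentate granule layer markers and held 59 and 79 spots in mouse 1 and mouse 2. The Spink8 region carried 6 of 7 CA1 markers, and the Hpca-Neurod6 region 7 of 9 CA2/CA3 markers; together they are called the CA-set regions. Among its 10 strongest genes the Spink8 region had 3 markers of the neuropil set (Hpca, Itpka and Wipf3) and 2 of CA1 (Pou3f1 and Spink8). Those of the Hpca-Neurod6 region held the neuropil marker Hpca and the layer 6 marker Crym, but no CA2/CA3 marker. The CA-set regions are therefore cell layers by their marker sets only. The Ddn region carried 7 of 8 hippocampal neuropil markers and held 412 and 359 spots. These 4 clusters are called the hippocampal regions. The neocortical regions were the Vxn region, with 5 of 7 layer 6 markers, and the Lamp5-Tshz2 region, with 3 of 5 retrosplenial markers. A further Lamp5-led cluster was left unnamed, with 347 of 3712 spots in mouse 1 and 180 of 3548 in mouse 2, so upper neocortical layers are largely outside the comparison. The thalamus-set regions were 4 clusters, and the white matter regions were 2 clusters, each with 8 of 8 white matter markers. The Ttr-led cluster took its name from 6 of 7 markers of meninges and large vessels, but 5 of its 10 strongest genes (Ttr, Enpp2, Kl, Folr1 and Clic6) are choroid plexus markers and 2 (Igf2 and Mgp) meningeal ones. A spot mixes several cells, so the regions are areas of tissue and not cell types. The lists likewise group genes and not cells, and other cells in a spot can express their members.

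**Figure D1:**
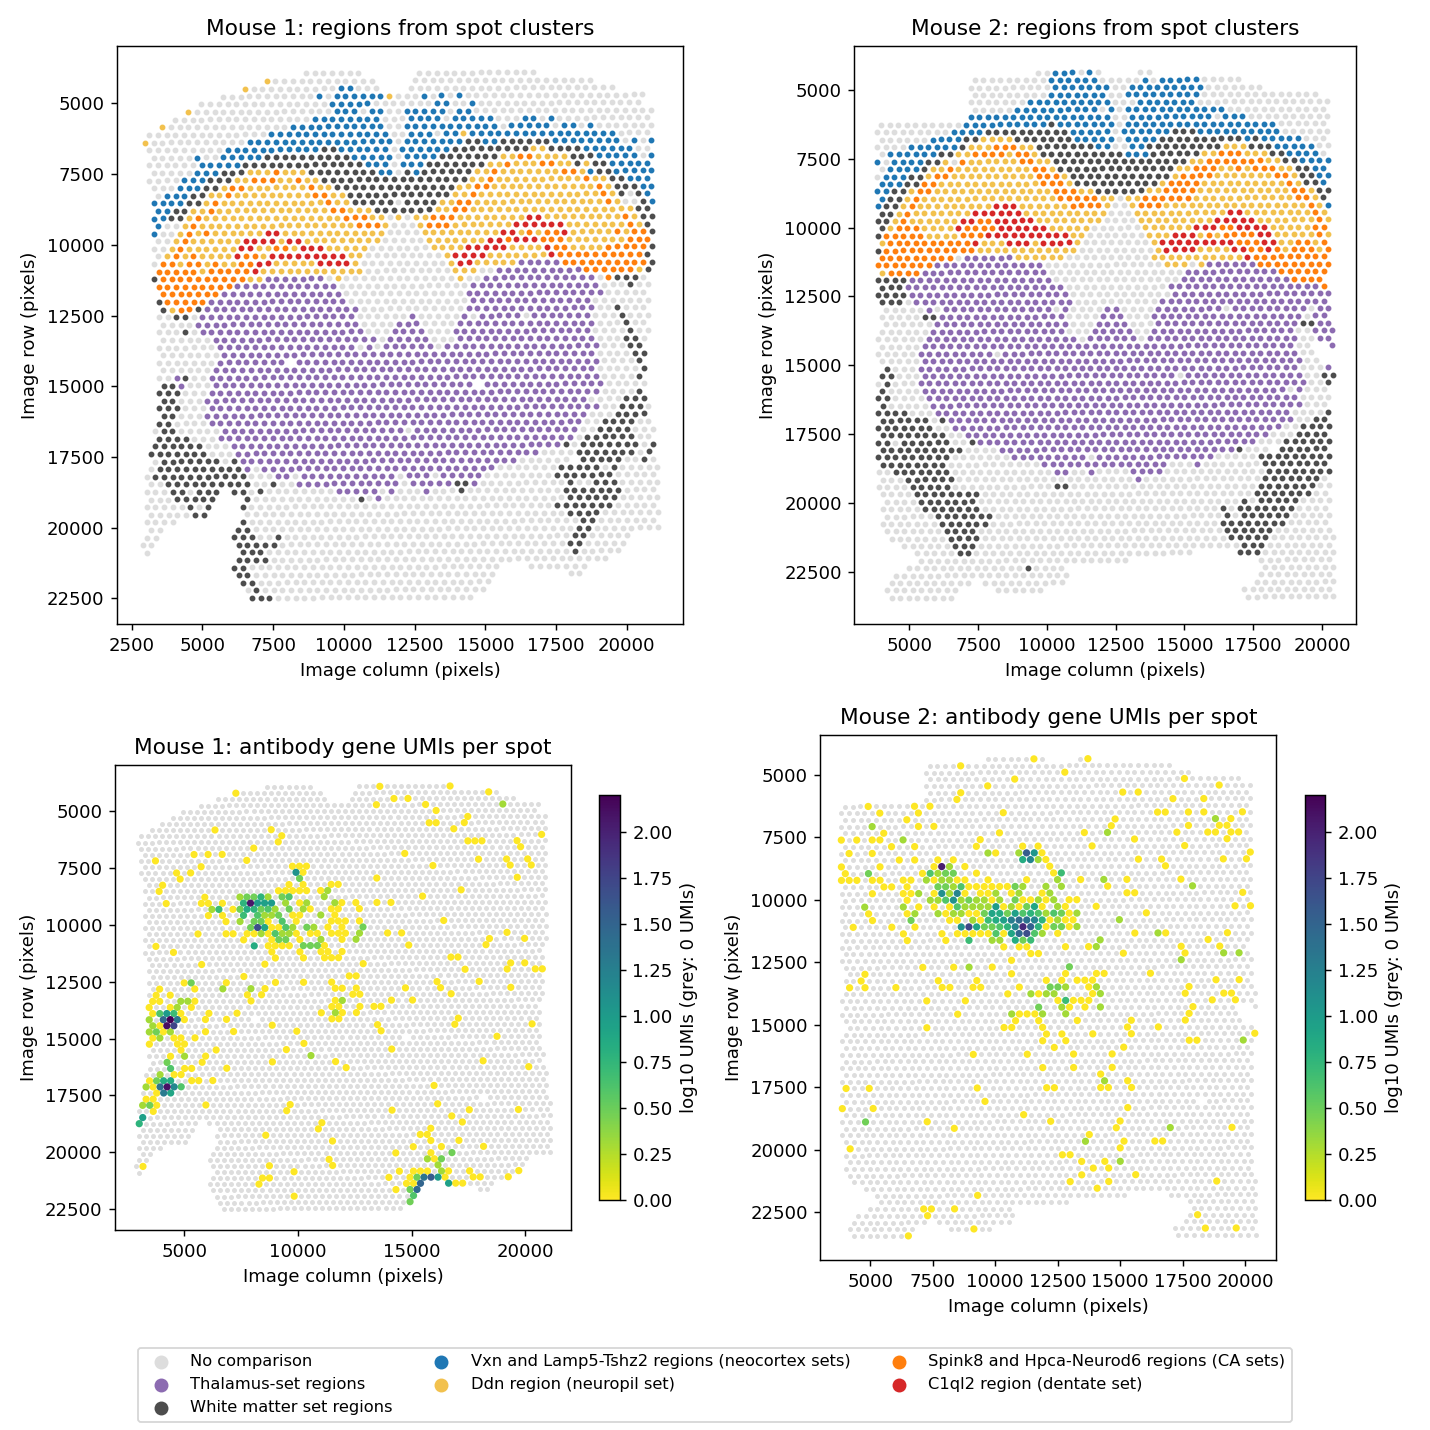
Array spots of both sections at their image positions in pixels, coloured by region in the upper panels and by the log10 UMI count of antibody genes in the lower panels (grey, 0 UMIs). Spots rich in antibody genes lie mainly on the image left, with 1259 antibody gene UMIs on the left and 289 on the right in mouse 1, and 1063 and 219 in mouse 2.

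Complement component C1q, the recognition molecule of the classical complement pathway, was detected in every named region through its genes C1qa, C1qb and C1qc. C1qa (ENSMUSG00000036887; mm10 chromosome 4, 136895916 to 136898844) was, among the compared regions, highest in the white matter regions at 163 ± 25.8 CPM (UMI counts scaled to the library total; SD, n = 2 mice here and below). It stood at 105 ± 12.5 CPM in the Ddn region, 55.3 ± 1.3 in the C1ql2 region and 53.9 ± 6.25 in the CA-set regions. The neocortical regions held 58.0 ± 0.980 CPM and the thalamus-set regions 57.6 ± 8.05. C1qb (ENSMUSG00000036905; chromosome 4, 136880126 to 136886200) and C1qc (ENSMUSG00000036896; chromosome 4, 136889801 to 136892936) were likewise highest there, at 158 ± 18.6 and 140 ± 14.1 CPM, and next in the Ddn region, at 99.2 ± 1.60 and 83.5 ± 6.66 CPM. C4b (ENSMUSG00000073418; chromosome 17, 34728139 to 34743902), the complement component cleaved downstream of C1q, stood at 75.6 ± 18.8 CPM in the white matter regions and 24.4 ± 5.66 in the Ddn region. Outside the compared regions, the Ttr-led cluster, a mix of choroid plexus and meningeal tissue by its genes, held 163 ± 0.196 CPM of C1qa and 93.9 ± 35.3 of C4b. CPM are shares of the RNA counted in a region and not molecules per spot. Median UMIs per spot ran from 4720.5 in the Ddn region to 9326 in the thalamus-set regions of mouse 1. In mouse 2 they ran from 10895 to 18780 in the same regions.

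Immunoglobulin transcripts were uneven between regions and mice. Igkc (ENSMUSG00000076609; chromosome 6, 70726435 to 70726754), the constant region of the kappa light chain, stood at 91.3 ± 55.0 CPM in the Ddn region, 60.5 ± 22.5 in the C1ql2 region and 8.09 ± 0.478 in the CA-set regions. It stood at 34.3 ± 32.9 CPM in the white matter regions, 5.15 ± 0.348 in the thalamus-set regions and 1.58 ± 0.185 in the neocortical regions. Ighm (ENSMUSG00000076617; chromosome 12, 113418826 to 113422730), the mu heavy chain, had another pattern, with 115 ± 7.74 CPM in the neocortical regions. The Vxn region held 170 ± 3.52 CPM, and Ighm is itself among the 3 strongest leading genes of that cluster, although listed genes were left out of the clustering. Among gamma heavy chains, Ighg1 had 32 UMIs in mouse 1 and 0 in mouse 2, where a count of 0 allows up to 3 UMIs. Ighg3 and Ighe had 0 UMIs in both mice. No gene of the B and plasma cell list reached the minimum count for a test in any comparison.

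**Figure D2:**
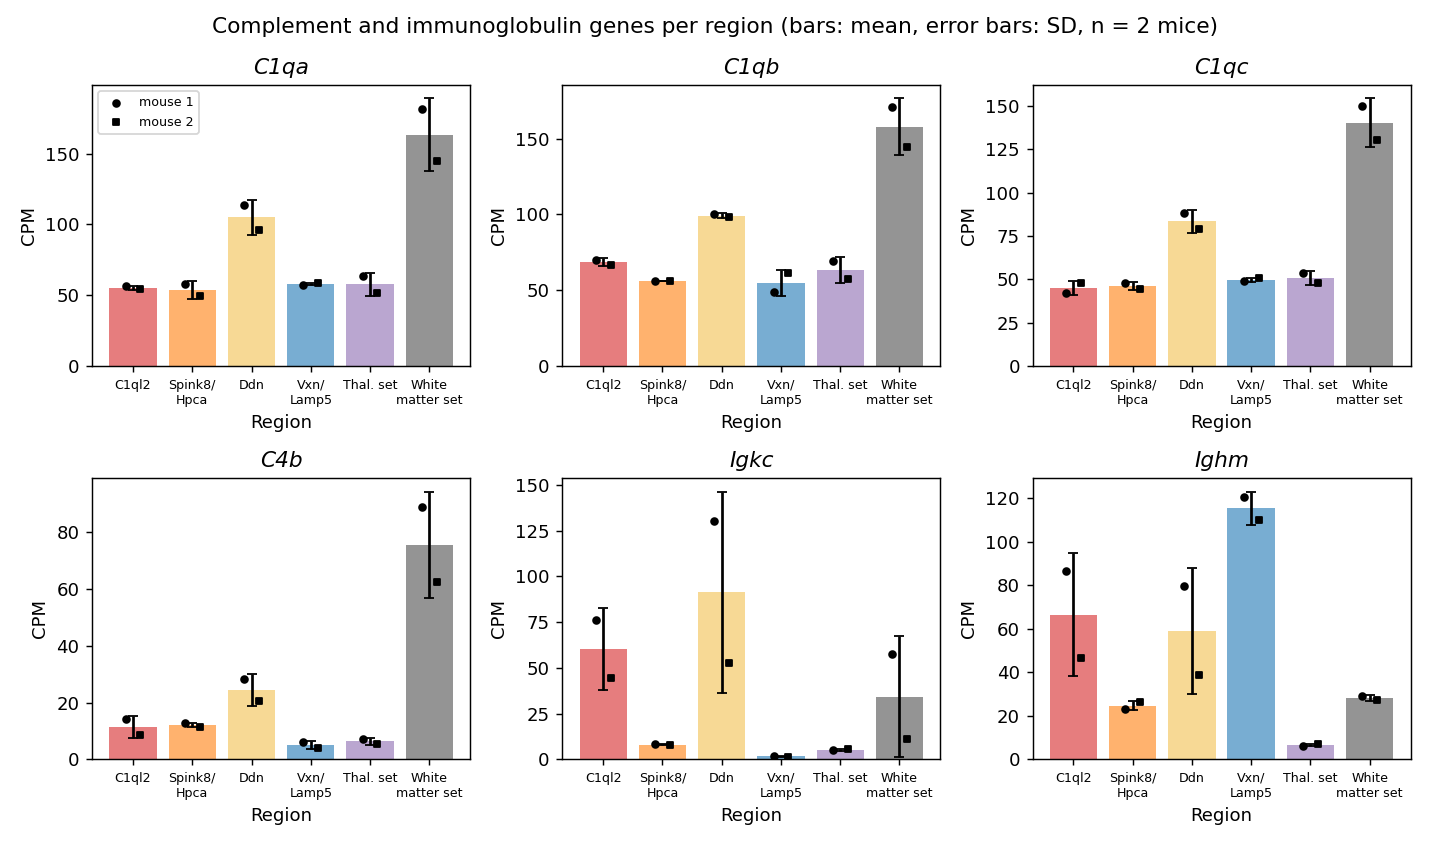
Levels in CPM of C1qa, C1qb, C1qc, C4b, Igkc and Ighm per region; bars are means over 2 mice, error bars the SD, circles mouse 1 and squares mouse 2. C1qa ranged from 53.9 CPM in the CA-set regions to 163 CPM in the white matter regions, and Igkc from 1.58 CPM in the neocortical regions to 91.3 CPM in the Ddn region.

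The medial entorhinal cortex, which lies near the injection level, projects to the dentate gyrus, and the C1ql2 region was compared with the CA-set regions to ask where the listed genes differed between cell layers. Jun, an AP-1 transcription factor gene, was 5.78-fold higher in the C1ql2 region, at 132 ± 36.4 CPM against 24.0 ± 6.13 (log2 2.53 ± 0.18 SE, adjusted p = 1.02e-40 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, higher in both mice). Each SE of a log2 value, here and below, rests mainly on a spread pooled over genes and does not give the spread between mice. Btg2, an antiproliferative early response gene, was higher by a log2 value of 2.77 ± 0.37. Of 13 immediate early genes tested, these 2 were higher, 5 were lower and 6 did not pass. Nr4a3, an orphan nuclear receptor gene, fell by 1.66 ± 0.23 on the log2 scale. Egr1 and Arc, chosen after their values were seen, fell by 1.0 ± 0.16 and 0.90 ± 0.32; Arc lost its call with DESeq2, without the mouse term and after thinning. Fos, also chosen after its values were seen, differed by a log2 value of -0.92 ± 0.58 without passing (adjusted p = 0.295) and stood at 0.53 with regions drawn by marker scores. Of 11 late activity-regulated genes, 2 were higher and 4 lower, among them Sorcs3 at -1.72 ± 0.28, Rasgrp1 at -1.27 ± 0.15 and Homer1 at -0.67 ± 0.17.

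C1q genes did not pass in this comparison of cell layers, at log2 values of 0.15 ± 0.20 for C1qa (adjusted p = 0.684), 0.34 ± 0.18 for C1qb (0.202) and 0.09 ± 0.21 for C1qc (0.847). None of the 4 classical complement genes, 12 homeostatic microglia genes, 3 Fc receptor genes, 6 oligodendrocyte precursor genes or 4 interferon genes tested passed edgeR's test, while 1807 of all 10244 genes passed and 2926 had an unadjusted p under 0.05. All 3 immunoglobulin genes tested were higher in the C1ql2 region: Igkc by a log2 value of 2.83 ± 0.28 (7.11-fold, adjusted p = 9.96e-21), Igha by 3.06 ± 0.43 and Ighm by 1.29 ± 0.22, each in both mice. Of the Igkc UMIs of the C1ql2 region, 37 and 67 lay on the image left and 1 and 1 on the right, so the difference is carried by 1 side. Presynaptic genes were lower there in 10 of 14 cases (13 of 14 when adjusted over the list alone), including Bsn at -0.97 ± 0.16, Stx1a at -1.07 ± 0.26 and Syt1 at -0.78 ± 0.16. Excitatory postsynaptic genes were lower in 7 of 15 cases (8 adjusted over the list alone), including Shank1 at -0.74 ± 0.19, Nlgn1 at -0.74 ± 0.24 and Gria3 at -0.70 ± 0.16. Npy, a neuropeptide of interneurons, was higher by 1.18 ± 0.14 and Cck lower by a log2 value of -1.30 ± 0.18, out of 2 higher and 4 lower among 14 inhibitory genes. Lpl, a lipoprotein lipase gene, fell by 2.0 ± 0.27, and Ctsb fell by 0.43 ± 0.15, out of 10 genes of activated microglia of which 8 did not pass. Sez6 fell by 1.20 ± 0.17 and Nptxr by 0.83 ± 0.15, while 10 of 12 complement regulators and receptors did not pass. S100b fell by 0.54 ± 0.15 as 1 of 9 astrocyte genes, Vim was higher by 0.83 ± 0.31 as 1 of 3 reactive astrocyte genes, and 4 of 10 phagocytosis signals were lower. The Vim call was lost under 8 alternatives, at values from 0.18 to 0.91. Nptxr and S100b lost theirs under 3, with values of -0.07 and -0.11 where regions were drawn by marker scores. Ctsb, Homer1 and Nlgn1 also lost theirs under 3 alternatives each, Stx1a, Shank1 and Gria3 under 2, Npy with DESeq2 and Syt1 without the mouse term.

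Blood genes moved in the same comparison: all 4 tested were lower in the C1ql2 region, with Hbb-bs, chosen after its values were seen, at -1.47 ± 0.16. Of the remaining lists, 1 of 7 endothelial genes was lower, 1 stress gene was higher and 2 lower of 8, and Xist, the only sex-linked gene tested, was higher by 1.05. In all, 952 genes were higher and 855 lower of 10244 tested, and 12 and 46 of the 163 listed genes. The camera test of whole lists with a preset correlation of 0.01 called 4 of 19 lists, namely the immunoglobulin, presynaptic, excitatory postsynaptic and blood lists. With an estimated correlation their adjusted p by camera was 0.675 and 0 of 19 were called, which decides nothing with 1 residual degree of freedom. Under all alternatives that gave a value, 14 of the 26 genes followed and called here kept their call. The median was positive while the mean and camera's direction were negative for the complement regulators (0.12 and -0.03) and the endothelial genes (0.11 and -0.14).

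Synapses lie mostly in the neuropil, so the Ddn region was compared with the C1ql2 and CA-set regions together. A spot of the Ddn region held a median of 4720.5 UMIs in mouse 1 and 10895 in mouse 2. The medians were 8180 and 18736 in the C1ql2 region and 8100 and 17206 in the CA-set regions. Higher values in the Ddn region are therefore larger shares of the counted RNA, and counts per spot were not compared. C1qa was 2.15-fold higher in the Ddn region, at 105 ± 12.5 CPM against 54.3 ± 4.86 (log2 1.10 ± 0.11 SE, adjusted p = 4.59e-22 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, higher in both mice). C1qb was 1.86-fold higher (adjusted p = 4.4e-15) and C1qc 2.0-fold higher (8.19e-16), also in both mice. C4b was higher by a log2 value of 1.17 ± 0.22, a call lost with DESeq2 and with regions drawn by marker scores. Of 5 classical complement genes tested, 4 were higher and 1 did not pass. Complement regulators went both ways, with 3 of 15 higher and 5 lower; Itgam, a subunit of complement receptor 3, was higher by 1.56 ± 0.32, a call lost with regions drawn by marker scores, and Clu (clusterin) by 1.24 ± 0.06.

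Many microglial, astrocytic and immunoglobulin genes were higher in the Ddn region. Of 14 homeostatic microglia genes 12 were higher (14 adjusted over the list alone), led by Gpr34 at 1.39 ± 0.22, Olfml3 at 1.34 ± 0.17 and Siglech at 1.25 ± 0.21. Of 6 Fc receptor and adaptor genes 5 were higher (6 adjusted over the list alone), including Fcgrt, the neonatal Fc receptor, at 1.47 ± 0.28, Fcgr1 at 1.28 ± 0.51, a call lost under 4 alternatives, and Tyrobp at 1.13 ± 0.11. Activated microglia genes were higher in 9 of 11 cases and lower in 1, with Mertk, a phagocytic receptor, at 1.65 ± 0.21, Spp1 at 1.39 ± 0.46 and Cd63 at 1.3 ± 0.09. All 10 astrocyte genes were higher, including the water channel gene Aqp4 at 1.68 ± 0.10, Sox9 at 1.53 ± 0.16 and Aldh1l1 at 1.32 ± 0.21. Gfap (ENSMUSG00000020932; chromosome 11, 102887336 to 102897200), an intermediate filament gene of astrocytes, was 3.23-fold higher (212 ± 19.2 CPM against 72.6 ± 3.31), and of 5 reactive astrocyte genes 3 were higher and 1 lower. All 4 immunoglobulin genes tested were higher, with Igkc, of which 265 and 206 UMIs lay on the image left and 5 and 7 on the right, at 2.02 ± 0.14, or 4.05-fold, Jchain (ENSMUSG00000067149; chromosome 5, 88519809 to 88527897), the joining chain of polymeric antibody, at 1.92 ± 0.43 and Igha (ENSMUSG00000095079; chromosome 12, 113256204 to 113260236), the alpha heavy chain, at 1.65 ± 0.23. Pf4, the single border macrophage gene tested, was higher by 2.50 ± 0.55. With regions drawn by marker scores Fcgrt (0.44), Aldh1l1 (0.46), Spp1 (0.29), Sox9 (0.63) and Jchain (1.11) lost their calls, and Spp1 also without the mouse term.

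Neuronal transcripts went the other way or divided. Bdnf, an activity-regulated growth factor gene, fell by 1.34 ± 0.13 in the Ddn region, as 1 of 4 late activity-regulated genes that were lower while 1 of 12 was higher. Presynaptic genes were lower in 9 of 14 cases and higher in 1, and excitatory postsynaptic genes lower in 7 of 15 and higher in 3. Among 15 immediate early genes Egr1 was higher by 0.49 ± 0.08, Nr4a3 and Jun were lower by log2 values of -0.81 ± 0.14 and -0.35 ± 0.13, and 12 did not pass; the Jun call was lost under 5 alternatives. Egr1 lost its call at 0.11 with each section clustered alone, and Nr4a3 at -0.14 with regions drawn by marker scores. Of 14 inhibitory genes 6 were higher and 4 lower, of 12 phagocytosis signals 3 and 2, and of 8 stress genes 1 and 6. All 7 oligodendrocyte precursor genes, 8 of 10 endothelial genes (9 adjusted over the list alone), all 6 interferon genes and all 5 blood genes were higher, with Hbb-bs, chosen after its values were seen, at 1.37 ± 0.06.

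Of 11927 genes tested, 2076 were higher and 1925 lower in the Ddn region, and of 190 listed genes 93 and 41. Camera with its preset correlation called 14 of 19 lists and 0 with an estimated correlation, where the adjusted p ranged from 0.455 to 0.999. With DESeq2 21 of the 30 genes followed and called kept their call, 7 having no value there, and with regions drawn by marker scores 19 of the 28 that had a value. Under all alternatives that gave a value 18 of 30 kept it.

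Hippocampal and neocortical regions of the same sections were compared to ask whether the hippocampus differed from other cortex. Spots of the hippocampal regions held medians of 5557.5 and 12869 UMIs in the mice, against 8981.5 and 16097.5 in the neocortical regions. Higher values are therefore larger shares of the counted RNA, and counts per spot were not compared. Gfap was 4.82-fold higher in the hippocampal regions, at 139 ± 19.1 CPM against 28.4 ± 1.48 (log2 2.27 ± 0.11 SE, adjusted p = 1.65e-87 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, higher in both mice), and Serpina3n, a protease inhibitor gene of reactive astrocytes, was 5.81-fold higher. C4b was 3.62-fold higher, at 18.0 ± 4.33 CPM against 5.05 ± 1.33. C1q genes were higher by smaller amounts, C1qa by a log2 value of 0.42 ± 0.10 (adjusted p = 0.00031), C1qb by 0.49 ± 0.10 (2.03e-05) and C1qc by 0.36 ± 0.11 (0.00513), in both mice. These 3 calls depended on the method: C1qa lost its call under 7 alternatives, with values from 0.14 to 0.45, and C1qb and C1qc under 4 alternatives each, DESeq2 among them for all 3 genes. Of 6 classical complement genes 5 were higher and 1, C1ra at -1.40 ± 0.51, was lower; Serping1, the C1 inhibitor gene, was higher by 2.08 ± 0.50. C1ra lost its call under 4 alternatives and Serping1 under 3, DESeq2 and regions drawn by marker scores among them for both, the last at values of -0.0045 and 0.67. Of 16 complement regulators 4 were higher, including Nptxr, a pentraxin receptor gene, at 0.99 ± 0.09 and Itgam at 0.83 ± 0.31, the last call being lost under 9 alternatives.

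Immunoglobulin genes split between these regions. Igkc was 32.7-fold higher in the hippocampal regions, at 56.7 ± 33.1 CPM against 1.58 ± 0.185 (log2 5.03 ± 0.25, adjusted p = 3.99e-84, both mice), with 320 and 310 UMIs in the hippocampal regions of mouse 1 and mouse 2 against 4 and 6. The difference is carried by the image left: on the right the hippocampal regions held 3.02 and 2.48 CPM in the mice, against 1.82 and 1.40 in the neocortical regions. Igha was higher by 4.59 ± 0.44, and Jchain had 30 and 35 UMIs against 1 and 1. Ighm and Ighg2c, chosen after their values were seen, were lower in the hippocampal regions, by log2 values of -1.34 ± 0.10 and -3.27 ± 0.49. The Ighm difference came to 0.47 in the opposite direction, past the threshold, when regions were named from 50 leading genes instead of 100, and the call of Ighg2c was lost with regions drawn by marker scores.

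Among glial groups 7 of 14 homeostatic microglia genes were higher in the hippocampal regions (10 adjusted over the list alone), with Siglech at 0.82 ± 0.20, P2ry12 at 0.77 ± 0.15 and Ctss at 0.73 ± 0.10, and none was lower; the Siglech call was lost under 3 alternatives and that of P2ry12 with DESeq2. Tyrobp was higher by 0.64 ± 0.10 and Fcer1g by 0.41 ± 0.16, out of 5 Fc receptor and adaptor genes; the Fcer1g call was lost under 7 alternatives, at values from 0.12 to 0.46. Of 11 activated microglia genes 4 were higher and 2 lower, with Lpl at 2.87 ± 0.21, Apoe at 0.65 ± 0.10 and Mertk at 0.47 ± 0.19, a call lost under 11 alternatives. Astrocyte genes were higher in 4 of 10 cases, including Aqp4 at 1.40 ± 0.11, Sox9 at 0.56 ± 0.15 and the glutamate transporter gene Slc1a3 at 0.51 ± 0.09; with regions drawn by marker scores Aqp4 and Apoe lost their calls at 0.05 and 0.04, and the Sox9 call was lost under 4 alternatives. Of 5 reactive astrocyte genes 4 were higher, among them Cp at 1.44 ± 0.43, a call lost under 7 alternatives, at values from 0.33 to 1.48. Pf4 stood at 0.85 ± 0.47 and did not pass, except with each section clustered alone, at 2.14.

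Neuronal groups also differed between the hippocampal and neocortical regions. Fos, a transcription factor gene induced by activity, fell by 1.28 ± 0.22 in the hippocampal regions, at 7.88 ± 0.533 CPM against 19.5 ± 2.01, and Dusp1 fell by 1.17 ± 0.22, while Jun was higher by 0.90 ± 0.13; Dusp1 and Jun lost their calls with DESeq2. Of 16 immediate early genes 3 were higher and 4 lower. Egr1, chosen after its values were seen, fell by 0.81 ± 0.08 and Arc, chosen likewise, differed by -0.28 ± 0.15 without passing (adjusted p = 0.156); both came out slightly higher when 50 leading genes were searched, at 0.05 and 0.10. Egr1 lost its call at -0.02 with regions drawn by marker scores, while Arc passed as lower under 4 alternatives, at values from -0.48 to -0.34. Excitatory postsynaptic genes were higher in 9 of 15 cases (10 adjusted over the list alone) and lower in 1, and presynaptic genes lower in 10 of 14 and higher in 1. Of 12 phagocytosis signals 7 were lower and none higher, of 12 late activity-regulated genes 5 were higher and 3 lower, and of 14 inhibitory genes 4 and 5. None of 10 endothelial genes and none of 5 blood genes passed edgeR's test, while 3681 of all 12496 genes passed and 4693 had an unadjusted p under 0.05. Of 7 interferon genes 4 were higher, of 8 stress genes 2 were higher and 3 lower, and 1 of 7 oligodendrocyte precursor genes was lower.

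Of 12496 genes 1858 were higher and 1823 lower in the hippocampal regions, and of 194 listed genes 61 and 39. Camera called 7 of 19 lists with its preset correlation, and 0 with an estimated correlation, where the lowest adjusted p was 0.661. Median and mean differed in sign for inhibitory genes (-0.08 and 0.04) and stress genes (-0.10 and 0.06), with camera's direction down for both, and down also for blood genes at a median of 0.01. With DESeq2 17 of the 31 genes followed and called kept their call, with regions drawn by marker scores 18, and under all alternatives that gave a value 12.

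Against the thalamus-set regions, the hippocampal regions were higher in C1qa by a log2 value of 0.57 ± 0.09 SE (1.48-fold, adjusted p = 2.3e-10 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), in C1qb by 0.45 ± 0.09 and in C1qc by 0.45 ± 0.09, each in both mice. For C1qa the difference in CPM lay in the Ddn region, at 105 CPM. The C1ql2 and CA-set regions held 55.3 and 53.9 CPM against 57.6 in the thalamus-set and 58.0 in the neocortical regions. Spots of the hippocampal regions held medians of 5557.5 and 12869 UMIs in the mice, against 9326 and 18780 in the thalamus-set regions. The C1q differences are therefore in shares of the counted RNA, and counts per spot were not compared. C4b was 3.01-fold higher and Serping1 2.02-fold higher, so that 5 of 6 classical complement genes were higher and 1 did not pass; the Serping1 call was lost with DESeq2 and after thinning. Egr4, a transcription factor gene induced by activity, was 19.2-fold higher, at 24.4 ± 0.133 CPM against 1.34 ± 0.122, and Egr2 had 8 and 26 UMIs against 1 and 0. Of 16 immediate early genes 12 were higher and 3 lower; among those chosen after their values were seen, Arc was higher by 1.94 ± 0.15 and Egr1 by 1.73 ± 0.08, and Fos fell by 0.86 ± 0.17. The Fos call was lost with DESeq2 and, at -0.40, with regions drawn by marker scores. Nptx1, a secreted pentraxin gene of synapses listed with the complement regulators, stood at 197 ± 35.0 CPM against 13.2 ± 2.08 and was higher by 4.01 ± 0.10. Csmd2 was higher by 1.71 ± 0.20 and Srpx2 lower by a log2 value of -1.53 ± 0.54, a call lost with DESeq2, out of 8 higher and 5 lower among 18 regulators.

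All 4 immunoglobulin genes tested were higher in the hippocampal than in the thalamus-set regions: Igkc 10.2-fold, Igha 13.5-fold and Jchain 9.15-fold, with Ighm, chosen after its values were seen, 7.21-fold. The Igkc excess lay on the image left, since on the right the hippocampal regions held 3.02 and 2.48 CPM against 2.85 and 5.43 in the thalamus-set regions. Of 14 homeostatic microglia genes 12 were higher, with Aif1 at 1.09 ± 0.11, P2ry12 at 0.92 ± 0.11 and Siglech at 0.92 ± 0.15. Fcer1g, Tyrobp and Fcgr3 were higher by 0.95 ± 0.13, 0.79 ± 0.09 and 0.74 ± 0.16, out of 4 higher among 7 Fc receptor and adaptor genes. Lpl was higher by 3.10 ± 0.15 and Mertk by 1.25 ± 0.15, while Spp1 fell by 1.29 ± 0.22, out of 6 higher and 1 lower among 13 activated microglia genes. Among border macrophage genes Mrc1 passed at 0.96 ± 0.38 although mouse 1 stood at -0.01 and mouse 2 at 1.24, a call lost under 5 alternatives, and F13a1 was lower at -1.78 ± 0.61. Astrocyte genes divided, 3 higher and 4 lower of 10: Slc1a3 was higher by 1.05 ± 0.08, and Gjb6 and S100b were lower, at -0.74 ± 0.09 and -0.63 ± 0.09. Of 9 reactive astrocyte genes 5 were higher (6 adjusted over the list alone) and 1 lower. Gfap was 8.17-fold and Serpina3n 7.4-fold higher, and Cxcl10, an interferon-induced chemokine gene, passed at 1.81 ± 0.47 on the strength of mouse 1 (2.12, against -0.05 in mouse 2). Calls were lost for Fcgr3, F13a1 and Cxcl10 with DESeq2, for Cxcl10 also without the mouse term, and for Spp1, at -0.51, with regions drawn by marker scores.

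Inhibitory genes were higher than in the thalamus-set regions in 10 of 14 cases and lower in 3, excitatory postsynaptic genes higher in 9 of 15 (10 adjusted over the list alone) and lower in 1, and presynaptic genes higher in 3 of 14 and lower in 7. Late activity-regulated genes were higher in 7 of 12 cases and lower in 3, phagocytosis signals 4 and 4 of 12, and stress genes 3 and 4 of 8. Of 10 interferon genes 6 were higher and none lower, while 3 of 7 oligodendrocyte precursor genes, 2 of 10 endothelial genes and 1 of 5 blood genes were lower. In all 3889 genes were higher and 3884 lower of 14112, and 103 and 43 of 208 listed genes. Camera called 8 of 20 lists with its preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.616). Median and mean differed in sign for border macrophage genes (0.62 and -0.07, camera up) and stress genes (-0.18 and 0.23, camera down). With DESeq2 27 of the 34 genes followed and called kept their call, and under all alternatives that gave a value 26.

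Among the compared regions, the white matter regions had the highest levels of C1q and C4b. C1qa was 2.35-fold higher there than in the hippocampal regions, at 163 ± 25.8 CPM against 78.7 ± 11.5 (hippocampal minus white matter log2 -1.23 ± 0.08 SE, adjusted p = 3.59e-46 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, in both mice), C1qb 2.25-fold and C1qc 2.48-fold. C4b was 4.76-fold higher in white matter, at 75.6 ± 18.8 CPM against 18.0 ± 4.33, and 4 of 5 classical complement genes were higher there with 1 not passing. Cd59a, an inhibitor of the membrane attack complex, and Itgb2, the beta subunit of complement receptor 3, were 3.64-fold and 3.52-fold higher in white matter. Nptxr was 3.96-fold higher in the hippocampal regions. Of 17 regulators 6 were higher in the hippocampal regions and 8 in white matter. Genes of the microglia lists were higher in white matter in 13 of 14 homeostatic cases, with Sall1 at -1.67 ± 0.20, Csf1r at -1.27 ± 0.10 and Ctss at -1.23 ± 0.08, and in 10 of 12 activated cases, with Cd9 at -2.34 ± 0.09 and Spp1 at -1.77 ± 0.27. Lpl was among the 2 of the activated list that were higher in the hippocampal regions, by 2.28 ± 0.19. Spp1 was also among the 10 strongest genes of the Pvalb-led cluster, so such values do not give the state of microglia. All 7 Fc receptor and adaptor genes were higher in white matter, including Trim21 at -1.69 ± 0.47, Fcgr1 at -1.31 ± 0.34 and Fcgr2b at -1.27 ± 0.37; these 3 calls were lost with DESeq2, and that of Fcgr2b also against the callosal cluster alone.

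Astrocyte genes were higher in white matter in 7 of 10 cases, with S100b at -2.06 ± 0.09, Megf10, a phagocytic receptor gene, at -1.89 ± 0.17 and Aqp4 at -0.79 ± 0.08. Aqp4 reversed to 0.21 when the callosal cluster stood alone for white matter. Of 9 reactive astrocyte genes 5 were higher in white matter and 1 in the hippocampal regions. Examples are Cxcl10 at -2.35 ± 0.35, Cd44 at -2.11 ± 0.39 and Ggta1 at -1.70 ± 0.49, and Gfap, chosen after its values were seen, at -1.54 ± 0.08. Cxcl10 and Ggta1 lost their calls with DESeq2, and Cxcl10 also, at -0.40, against the callosal cluster alone. All 7 oligodendrocyte precursor genes, with Sox10, chosen likewise, at -3.03 ± 0.11, all 10 endothelial, all 10 interferon and all 5 blood genes were higher in white matter. Neuronal groups were higher in the hippocampal regions: all 15 excitatory postsynaptic genes, with Camk2a, chosen after its values were seen, at 2.52 ± 0.09, 13 of 14 presynaptic genes, 10 of 12 late activity-regulated genes and 9 of 15 immediate early genes, including Nr4a3 at 2.29 ± 0.16, Egr3 at 1.76 ± 0.12 and Egr4 at 1.51 ± 0.20. Inhibitory genes were higher there in 7 of 14 cases and lower in 3, phagocytosis signals 3 and 7 of 12, and stress genes 5 and 1 of 8. The border macrophage genes Pf4 and Mrc1 did not pass, at -0.16 ± 0.41 and 0.08 ± 0.49.

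Immunoglobulin genes were unsettled against white matter. Igkc passed as higher in the hippocampal regions by 0.71 ± 0.12 and Jchain by 0.99 ± 0.40, but their calls were lost under 2 and 7 alternatives and both reversed with regions drawn by marker scores, at -0.17 and -0.01. Igkc lay on the image left in white matter too, with 171 and 53 UMIs against 2 and 3 on the right. Igha, chosen after its values were seen, passed at 0.65 ± 0.22 with the mice opposite, at -1.37 in mouse 1 and 4.03 in mouse 2, and lost its call under 7 alternatives and reversed to -0.28 with regions drawn by marker scores. Ighm, chosen likewise, passed at 0.48 ± 0.12 and stood at -0.14 against the callosal cluster alone; it lost its call with DESeq2 and without the mouse term. Ighg2b had 2 and 0 UMIs in the hippocampal regions against 12 and 29 in white matter, a call lost with DESeq2. The list's median was 0.65 and its mean -0.45, with camera's direction up, and the complement regulators likewise had a median of 0.03, a mean of -0.09 and camera up. In all 3318 genes were higher and 3399 lower in the hippocampal regions of 12807, and 75 and 102 of 204 listed genes. Camera called 15 of 19 lists with its preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.448). With DESeq2 24 of the 33 genes followed and called kept their call, and under all alternatives that gave a value 22.

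The injection was on 1 side of the brain, but the labels do not give which image side is ipsilateral, so the sides are image sides. Igkc was 35.1-fold higher on the image left than on the right of the hippocampal regions, at 112 ± 63.8 CPM against 2.75 ± 0.377 (right minus left log2 -5.13 ± 0.20 SE, adjusted p = 4.66e-101 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Mouse 1 had 314 Igkc UMIs on the left and 6 on the right, a CPM ratio of 51.9 with an exact 95% interval from 23.6 to 143, and mouse 2 had 298 and 12, a ratio of 26.8 from 15.1 to 52.4. These intervals cover counting error only, and the adjusted p takes the image left of both mice as the same side. Igha was 17.7-fold, Jchain 8.45-fold and Ighm 1.53-fold higher on the left, so all 4 immunoglobulin genes tested were lower on the right. For Ighm this rests on mouse 1, at a ratio of 2.24 (1.69 to 2.99), against 1.13 (0.905 to 1.42) in mouse 2 with 167 and 159 UMIs, and its call was lost under 5 alternatives; these counts of lost calls between sides leave mouse 2 mirrored aside. Much of the antibody signal of the whole sections lay in 14 foci. These are single spots or groups of up to 9 touching spots with at least 10 antibody gene UMIs each. Mouse 1 had 6 foci on the left, 3 of them peaking in the hippocampal regions, and 1 on the right. Mouse 2 had 7 on the left, 5 of them peaking in the hippocampal regions, and 0 on the right. The largest focus of each mouse peaked in the Ttr-led cluster, with 423 antibody gene UMIs in mouse 1 and 299 in mouse 2. The largest that peaked in the hippocampal regions held 126 and 106. Without the foci and the spots around them, a choice made after the counts were seen, the Igkc ratio was 14.7 (6.45 to 41.2) in mouse 1 and 6.10 (3.18 to 12.7) in mouse 2. The Igha ratio was 3.81 (0.982 to 21.6) and 4.95 (2.27 to 11.9), and the Jchain ratio 2.67 (0.609 to 16.0) and 1.59 (0.297 to 8.55), so that Jchain in both mice and Igha in mouse 1 are left open. Ighm lost its call at -0.11, and so did Ttr at 0.42.

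C1q and activity genes did not differ detectably between the image sides of the hippocampal regions. Right minus left log2 values were 0.02 ± 0.10 for C1qa, -0.13 ± 0.10 for C1qb and -0.14 ± 0.11 for C1qc, and -0.12 ± 0.31 for Fos, 0.27 ± 0.19 for Arc, -0.05 ± 0.08 for Egr1 and 0.02 ± 0.43 for Npas4, each at an adjusted p of 0.999. In the direction of a higher right side Sncg (0.87 ± 0.20), Ttr (0.64 ± 0.09) and Enpp2 (0.61 ± 0.08) passed, and in the direction of a higher left side C1ql2 (-0.55 ± 0.13) and AY036118 (-0.47 ± 0.08). C1ql2 lost its call under 6 alternatives, among them that without the antibody foci, where it turned to 0.59. Sncg lost its call under 4, Ttr under 3, and AY036118 and Enpp2 under 2. Ttr, Enpp2, C1ql2 and Sncg are themselves leading genes of clusters. In all 3 genes were higher and 6 lower on the right of 12030, with 541 at an unadjusted p under 0.05. No gene outside the immunoglobulin list passed among the listed genes, while adjusted over the list alone 1 presynaptic gene was lower and 1 endothelial gene higher. DESeq2 called 2 genes, Igkc and Igha. With mouse 2 mirrored, 2 genes passed and the Igkc difference was -0.01, since opposite sides then cancel. In each section Igkc lay mainly on 1 side. Whether that side is the same in both mice depends on how the sections were imaged. UMIs of 1 focus are not independent, so the intervals do not cover the placement of a few foci. The adjusted p-values of antibody genes between sides, by edgeR and by camera, do not cover it either, here and in single regions. Camera called the immunoglobulin, excitatory postsynaptic and blood lists with its preset correlation. For immunoglobulin genes its adjusted p was 9.67e-114, and 0.517 with an estimated correlation, where none of the 3 lists was called.

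**Figure D3:**
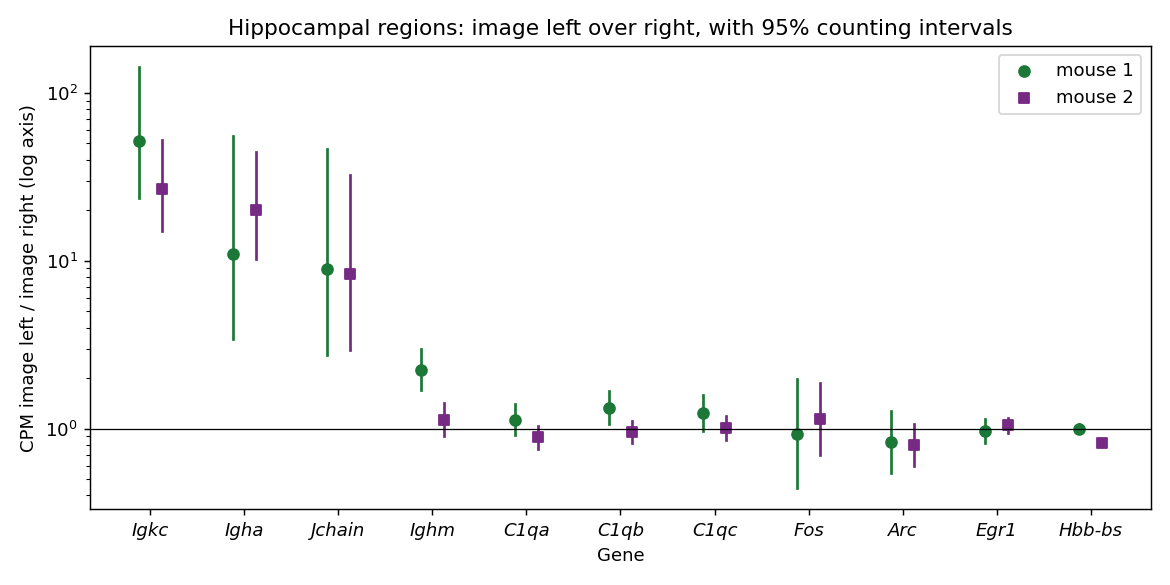
Ratio of CPM on the image left to that on the image right of the hippocampal regions, on a log axis, for 11 genes; circles are mouse 1, squares mouse 2, and bars 95% intervals of counting error. Igkc stands at 51.9 in mouse 1 and 26.8 in mouse 2, while C1qa, Fos, Arc and Egr1 lie near a ratio of 1.

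The single regions gave the same picture for Igkc. It was lower on the right in the C1ql2 region (1 and 1 UMIs on the right against 37 and 67), in the CA-set regions (-3.31 ± 0.66, with 0 and 4 UMIs against 12 and 25) and in the Ddn region (-5.39 ± 0.23, with 5 and 7 UMIs against 265 and 206; adjusted p = 1.92e-114 by edgeR's quasi-likelihood test). In the Ddn region Igha fell by 4.22 ± 0.38 on the right, Jchain by 3.20 ± 0.56 and Ighm by 0.97 ± 0.17. Without the antibody foci, calls were lost for Igha (-2.30) and Ighm (-0.22) in the Ddn region and for Igkc in the C1ql2 region. There 17 and 5 Igkc UMIs were left on the left against 1 and 1 on the right, as only 6 of 41 left spots of mouse 2 remained. Blood genes went both ways: all 4 tested were higher on the right in the CA-set regions, from Hba-a1 at 0.77 ± 0.12 and Hbb-bt at 0.73 ± 0.14 to Hbb-bs at 0.66 ± 0.11 and Hba-a2 at 0.54 ± 0.13. These calls were lost under 3, 3, 4 and 9 alternatives. In the C1ql2 region Hbb-bs, chosen after its values were seen, passed at 1.47 ± 0.22 with the mice opposite (-0.21 and 1.93), and lost its call under 3 alternatives. Adjusted over the list alone 3 blood genes were higher there, of which Hbb-bs and Hba-a1, the last chosen likewise, had the mice opposite (Hba-a1 at -1.19 and 1.33); Hba-a1 passed over all genes under 2 alternatives. In the same region, adjusted over the list alone and chosen after their values were seen, Nr4a3 was higher on the right (1.70 ± 0.50), and Gria3 (-0.91 ± 0.25) and Npy (-0.45 ± 0.13) were lower, each in both mice. None passed over all genes (adjusted p = 0.758, 0.679 and 0.698). In the Ddn region no blood gene passed, and 4 of 5 blood genes were lower on the right adjusted over the list alone, the direction of the antibody genes. Summed haemoglobin CPM there was 1.17 (1.10 to 1.24) and 1.13 (1.09 to 1.17) times as high on the left. Ttr and Enpp2, choroid plexus markers that lead the Ttr-led cluster, were higher on the right in the C1ql2 region (2.67 ± 0.11 and 1.47 ± 0.21) and the Ddn region (0.79 ± 0.10 and 0.82 ± 0.09), and Ttr was lower on the right in the CA-set regions (-0.60 ± 0.11), a call lost under 4 alternatives.

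Npy was higher on the right in the CA-set regions (0.65 ± 0.12) and lower there in the neocortical regions (-0.48 ± 0.09), where Ttr was lower as well (-0.44 ± 0.09) and the muscarinic receptor gene Chrm1 higher (0.74 ± 0.16). The Npy calls were lost under 3 and 2 alternatives, and those of Ttr and Chrm1 in the neocortical regions under 4 and 5. In the Ddn region the acetyltransferase gene Nat10 was higher on the right (2.48 ± 0.57, with 11 and 27 UMIs against 2 and 4) and AY036118 lower (-0.58 ± 0.10), calls lost under 6 and 2 alternatives. C1q genes stayed without a call in every region, with C1qa at 0.37 ± 0.30 in the C1ql2 region, -0.26 ± 0.20 in the CA-set regions, 0.05 ± 0.12 in the Ddn region and 0.07 ± 0.15 in the neocortical regions. C1qb stood at -0.47 ± 0.26, -0.27 ± 0.19, 0.00 ± 0.13 and 0.28 ± 0.16 in the same order, and C1qc at -0.26 ± 0.36, -0.43 ± 0.21, -0.02 ± 0.14 and -0.05 ± 0.17. Egr1 stood at 0.47 ± 0.24, -0.08 ± 0.13, -0.18 ± 0.10 and -0.18 ± 0.09, Fos at 0.48 ± 0.54 in the CA-set regions, -0.64 ± 0.43 in the Ddn region and -0.62 ± 0.27 in the neocortical regions, and Arc at -0.10 ± 0.27, 0.58 ± 0.28 and -0.58 ± 0.23.

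The numbers of genes higher and lower on the right were 3 and 1 of 6697 in the C1ql2 region, 5 and 2 of 9644 in the CA-set regions, 3 and 5 of 10415 in the Ddn region and 1 and 2 of 10459 in the neocortical regions, with 301, 430, 530 and 514 genes at an unadjusted p under 0.05. DESeq2 called 2, 0, 3 and 0 genes in these 4 regions, with 6, 10, 11 and 3 at an unadjusted p under 0.05. Leaving DESeq2, the fit without the mouse term and mouse 2 mirrored aside, 5 of 9 calls in the hippocampal regions as a whole were kept under every alternative that gave a value, and 1 of 4, 1 of 7, 5 of 8 and 1 of 3 in these 4 regions. Not every call had a value under each: without antibody foci 7 of the 8 Ddn calls had one and 4 were kept. With mouse 2 mirrored no call was kept. Camera with its preset correlation called the blood list in the C1ql2 and CA-set regions, the immunoglobulin and blood lists in the Ddn region, and the Fc receptor and inhibitory lists in the neocortical regions, none of them with an estimated correlation (lowest adjusted p = 0.924, 0.928, 0.567 and 0.901). Median, mean and camera direction differed in sign for 2, 3, 3 and 5 lists in the hippocampal regions as a whole, the C1ql2, the CA-set and the Ddn regions. Their medians lay between -0.11, for interferon genes in the Ddn region, and 0.07, for inhibitory genes in the C1ql2 region.

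The mice differed from each other in several gene groups, described without a test because each genotype label has 1 mouse. Ratios are of whole sections unless a region is named. The sections differed in make-up, with 347 and 180 spots in the unnamed Lamp5-led cluster and 101 and 210 in the Penk-led cluster. Random lists were matched on expression only, so a list of genes that vary together reaches an extreme percentile more easily. All 10 interferon genes were lower in mouse 2, at a median log2 ratio of -0.51, which lay at percentile 0 of 10000 random lists of matched expression; Ifi27l2a stood at -1.19 (95% interval -1.31 to -1.07), Oasl2 at -0.89 and Ifit3 at -0.85. All 6 immunoglobulin genes counted were lower too, at a median of -1.06 (percentile 0), with Jchain at -1.43 (-1.85 to -1.02). In the hippocampal regions Igha, chosen after its values were seen, went the other way, at 9.01 CPM in mouse 1 and 18.9 in mouse 2, so these ratios depend on the region. All 5 blood genes were higher in mouse 2, at a median of 0.94 (percentile 100), led by Hba-a1 at 1.75 and Hba-a2 at 1.66. All 15 excitatory postsynaptic genes were higher, at a median of 0.25 (percentile 100), with Shank3 at 0.90, Camk2b at 0.80 and Grin2b at 0.60, as were 10 of 12 late activity-regulated genes (0.26, percentile 99.99), among them Nptx2 at 0.55, 11 of 16 immediate early genes (0.16, percentile 97.4) and 13 of 14 presynaptic genes (0.13, percentile 99.06). Activated microglia genes were lower in 11 of 13 cases (-0.16, percentile 0.14) and homeostatic microglia genes in 9 of 14 (-0.05, percentile 1.26). Classical complement genes were lower in 6 of 9 cases (-0.14, percentile 1.44), with C4b at -0.63 (-0.77 to -0.49), and Fc receptor genes in 5 of 8 (-0.12, percentile 3.05).

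The other lists lay between percentiles 11.6 and 93.9, from reactive astrocytes at -0.05, with Cxcl10 at -1.56, to inhibitory genes at 0.11. Of single genes Oxt, which encodes oxytocin, was the lowest in mouse 2 at a log2 ratio of -7.11, with 2331 UMIs in mouse 1 and 30 in mouse 2, followed by Rtl8c at -3.81, Gm10076 at -2.74 and Hist2h2aa1 at -2.67. Lrrc17 was the highest at 3.32 (3.26 to 3.39), followed by Rpl36a-ps1 at 2.90, Amd2 at 2.32, Snhg9 at 2.27 and Tatdn1 at 2.2. Of 12646 genes with at least 200 UMIs, 62 were over 2-fold higher and 38 over 2-fold lower in mouse 2, the median absolute log2 ratio was 0.11, and Spearman's rho of CPM across genes, which are not independent replicates, was 0.992. In the hippocampal regions alone 49 genes were over 2-fold apart, and in the neocortical regions alone 25. The intervals cover counting error only, and genotype label, section and library cannot be separated with 1 mouse each.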

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

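All tests of explanations in this part were chosen after the results were seen. Ttr, a choroid plexus marker, moved in opposite directions between the sides of different regions in both mice; these differences between regions were not tested. The right minus left value of the C1ql2 region exceeded that of the CA-set regions by a log2 value of 3.27 and that of the neocortical regions by 3.11. The value of the CA-set regions minus that of the Ddn region was -1.39, and the Ddn region exceeded the neocortical regions by 1.23. Npy, an interneuron neuropeptide gene, was likewise opposite, with the CA-set regions above the neocortical regions by 1.13. Igkc had 505 UMIs in mouse 1 and 264 in mouse 2 in clusters outside the comparisons; it is given here because those clusters were not compared, and with no control section its level was not tested.

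Igkc, Igha and Jchain transcripts lay mainly on the image left of the hippocampal regions in both mice, and Ighm did so in mouse 1. Unequal blood in the unperfused tissue is argued against: the highest upper bound of left over right haemoglobin was 1.24, in the Ddn region of mouse 1, where the ratios were 1.17 and 1.13 in the mice, and haemoglobin was lower on the left of the hippocampal regions of mouse 2 (0.848, from 0.824 to 0.873). Foci of the size defined here are argued against as the whole cause for Igkc, where the lowest lower bound of the ratio without them was 3.18, and for Igha in mouse 2, at 2.27. These bounds cover counting error only, and smaller groups of antibody UMIs were not left out, so a few small sources stay open. Foci cannot be told apart from other causes for Igha in mouse 1 and for Jchain, where few UMIs were left and the lowest lower bounds were 0.982 and 0.297. Foci may account for Ighm in mouse 1: its ratio went from 2.24 (1.69 to 2.99) to 0.989 (0.697 to 1.40) without them. Reads carried between libraries are argued against, as at most 1.61% of a mouse's antibody UMIs lay at positions that were focus spots in the other. No biological explanation was tested, since the design has 1 group and the ipsilateral side is not given.

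Ighm was high in the Vxn region, at 170 CPM. The other neocortical region, Lamp5-Tshz2, held 32.8 CPM, less than the Ddn (59.1) and C1ql2 (66.5) regions, and with 50 leading genes the hippocampal against neocortical difference reversed to 0.47 past the threshold. In both neocortical regions together Igkc had 4 and 6 UMIs against 282 and 454 of Ighm. Antibody-secreting cells that use the kappa chain are argued against there, as the upper bound of Igkc over Ighm was 0.0367. Foci held 7.51 and 34.4 Igkc UMIs per Ighm UMI, but the genes that define foci include Igkc and leave out Ighm. Their ratio is therefore no yardstick. No biological explanation was tested.

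Between the mice, 100 genes were over 2-fold apart. Reads shared between paralogs or pseudogenes were looked at through gene symbols only. Predicted genes, pseudogenes, ribosomal protein genes and genes with symbols ending in Rik made up 25 of the 100 and 645 of the 12546 others. Their share was 4.86 times as high among the 100 (3.28 to 6.74). No reads were examined and the other genes were not matched on expression, so this share cannot decide whether shared reads played a part. After thinning, 76 genes were over 2-fold apart. Thinning keeps the expected ratio of each gene, so it cannot decide whether unequal depth played a part. Shared reads, depth, genotype label, section and library stay open.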

How the results depend on the processing

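The alternatives with 50 leading genes, the callosal cluster alone, the unnamed Lamp5 cluster added to neocortex, neuropil spots away from cell layers, antibody foci left out and the side change in each mouse were chosen after the data were seen. With 2 mice and 1 residual degree of freedom, the calls depend on a spread pooled over genes. Recovery of simulated 2-fold changes was lowest, at 18.6%, for the C1ql2 against the CA-set regions. The simulated dispersion was 0.02, above the 0.00649 of that fit, so this recovery is not that of the data. Of 3415 values of 229 pairs of gene and comparison under the alternatives, 2820 kept direction and side of the threshold, 266 lost their call, 7 gained one, 195 moved in single mice by more than the spread, and 127 reversed. The numbers of listed genes called against the thalamus-set (146) and white matter regions (177) stayed within 1.5-fold under every alternative run.

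Other counts moved, and the cause was not tested. C1ql2 against CA-set regions, 58 listed genes, gave 22 with DESeq2 and 25 without the mouse term; the Ddn region, 134, gave 72, 84 and, with marker score regions, 58; hippocampal against neocortical regions, 100, gave 50 and 63. Between sides, the hippocampal count of 9 became 2 with DESeq2, without the mouse term and with mouse 2 mirrored. The C1ql2 count of 4 became 2 with DESeq2, 1 without the mouse term and 2 without antibody foci. The CA-set count of 7 became 0 with DESeq2 and without the mouse term (10 and 207 genes at an unadjusted p under 0.05), 4 after thinning, 4 without a UMI minimum, 2 with at least 2000 UMIs and 3 with mouse 2 mirrored. The Ddn count of 8 became 3, 2 without the mouse term and 3 with mouse 2 mirrored. The neocortical count of 3 became 0 with DESeq2 and without the mouse term (3 and 287 at an unadjusted p under 0.05), 5 without the low-count filter, 1 without a UMI minimum and 1 with the midline moved left. The 100 genes over 2-fold apart between mice became 49 in the hippocampal and 25 in the neocortical regions alone, where fewer UMIs were counted. The summed C1q level of the hippocampal regions, 221.3 CPM (SD 20.5), came to 251.5 without mitochondrial genes, since the total is then smaller, and ranged from 206.9 to 235.8 without replicate 1 or without replicate 2.

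Most reversals were in values that had not passed a test. Mirroring mouse 2 also reversed called values, and so did 50 leading genes, marker score regions, the callosal cluster alone and leaving out antibody foci. Leaving out 1 mouse did so too, for Mrc1 and Cxcl10 against the thalamus-set regions, Igha against white matter and Hbb-bs between C1ql2 sides. The cause was not tested. With DESeq2: hippocampal against white matter (Mrc1 -0.034), hippocampal sides (C1qa -0.015, Npas4 -0.013), Ddn sides (C1qb -0.050). With DESeq2-style size factors: Ddn sides (C1qb -0.0012). With all regions in 1 fit: C1ql2 against CA-set (Tyrobp -0.012, Fcer1g -0.062). Without antibody foci: hippocampal sides (C1ql2 0.59, Npas4 -0.074), C1ql2 sides (C1qa -0.036), Ddn sides (C1qc 0.033). With at least 2000 UMIs: hippocampal against white matter (Mrc1 -0.26), CA-set sides (Arc 0.021), Ddn sides (C1qb -0.13), neocortical sides (C1qa -0.0081, C1qc 0.035). With the callosal cluster alone: hippocampal against white matter (Aqp4 0.21, Ighm -0.14). With each section clustered alone: C1ql2 against CA-set (C1qc -0.20, C1qa -0.12, Tyrobp -0.040, Fcer1g -0.10, Ctss -0.019), hippocampal against white matter (Pf4 0.10, Mrc1 -0.17). With 50 leading genes: hippocampal against neocortical (Ighm 0.47, Egr1 0.054, Arc 0.10). With marker score regions: C1ql2 against CA-set (C1qc -0.13, C1qa -0.13, Tyrobp -0.066, Fcer1g -0.15, Fos 0.53), hippocampal against neocortical (Pf4 -0.089, Arc 0.14), hippocampal against white matter (Jchain -0.0053, Igkc -0.17, Pf4 0.42, Igha -0.28). With the midline moved left: Ddn sides (C1qb -0.028). Without the midline strip: Ddn sides (C1qb -0.027). With mouse 2 mirrored, the reversed log2 values were, by comparison, hippocampal sides (Sncg -0.028, Enpp2 -0.23, Igha 1.94, Jchain 0.20, C1ql2 0.25, C1qa -0.14, Fos 0.19, Arc -0.085, Npas4 -0.12, Egr1 0.092), C1ql2 sides (Ttr -0.14, Enpp2 -0.48, Igkc 0.53, C1qa -0.53, C1qb 0.16, Egr1 -0.31, Hbb-bs -1.49, Nr4a3 -1.03, Gria3 0.46, Hba-a1 -1.35), CA-set sides (Hba-a1 -0.52, Hbb-bt -0.21, Hbb-bs -0.18, Npy -0.42, Hba-a2 -0.49, Igkc 0.81, C1qc 0.19, Fos -0.65, Arc 0.066, Egr1 0.065), Ddn sides (Nat10 -0.79, Enpp2 -0.20, Igha 1.67, C1qa -0.11, C1qb -0.23, Fos 0.92, Arc -0.14, Egr1 0.20), neocortical sides (Chrm1 -0.18, C1qa -0.019, C1qb -0.39, Fos 0.15, Arc 0.44, Egr1 0.11). Without a UMI minimum: C1ql2 against CA-set (Fcer1g -0.087), hippocampal against white matter (Mrc1 -0.52), Ddn sides (C1qb -0.040), neocortical sides (C1qc 0.011). Without the low-count filter: C1ql2 against CA-set (Tyrobp -0.0087, Fcer1g -0.053), Ddn sides (C1qb -0.0055). Without the mouse term: C1ql2 against CA-set (Fcer1g -0.036), hippocampal against white matter (Mrc1 -0.0045), hippocampal sides (C1qa -0.024), Ddn sides (C1qb -0.035). At resolution 0.6: C1ql2 against CA-set (Fcer1g -0.043), hippocampal against white matter (Pf4 0.39). At resolution 1.5: C1ql2 against CA-set (Fcer1g -0.027). After thinning: hippocampal sides (C1qa -0.082), Ddn sides (C1qa -0.037, C1qb -0.12).

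Without replicate 1 or without replicate 2, values with no test ranged as follows where 1 was reversed: C1ql2 against CA-set (C1qc -0.088 to 0.078, Tyrobp -0.16 to 0.29, Fcer1g -0.21 to 0.21), hippocampal against thalamus-set (Mrc1 -0.0070 to 1.24, Cxcl10 -0.046 to 2.12), hippocampal against white matter (Pf4 -0.37 to 0.32, Mrc1 -1.13 to 1.14, Igha -1.37 to 4.03), hippocampal sides (C1qa -0.17 to 0.13, C1qb -0.39 to 0.019, Fos -0.22 to 0.10, Npas4 -0.12 to 0.10, Egr1 -0.11 to 0.059), C1ql2 sides (C1qa -0.28 to 0.62, C1qc -1.45 to 0.23, Hbb-bs -0.21 to 1.93, Hba-a1 -1.19 to 1.32), CA-set sides (Fos -0.19 to 0.75), Ddn sides (C1qa -0.077 to 0.13, C1qb -0.29 to 0.16, C1qc -0.18 to 0.080, Fos -1.14 to 0.29, Egr1 -0.31 to 0.048), neocortical sides (C1qb -0.16 to 0.49, C1qc -0.21 to 0.036).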

Other observations

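Outside the compared regions, Igkc was unevenly spread between the mice, given as values with no test. The Ttr-led cluster held 316 Igkc UMIs in mouse 1 and 116 in mouse 2, the cluster of the habenula set 26 and 121, and the Hcrt-led cluster of the hypothalamus set 84 and 13.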
